A study of Rattus norvegicus with 150 samples.

How the data were processed

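The data were RNA-seq counts for 150 libraries of rat gastrocnemius muscle in 19 groups of metal and time. Per the labels' protocols, libraries were made from 1000 ng of total RNA with a stranded total RNA kit and read as pairs of 100 bases, with 10 samples in a lane. No lane or batch of any library was given. The deposited values are whole-number counts per gene, with no normalization. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to the rat build Rnor_6.0 and counted with featureCounts 1.5.0-p3. The annotation release and the strand setting were not given in the sources used here, so overlapping, antisense and near-identical genes may share reads. Every column was matched to a library by its label. The labels planned 8 rats per group but tie no library to a rat, so p-values measure the spread between libraries.

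The table names genes by Ensembl identifier. None of the 32545 identifiers could be paired with a name in the reference table used, which is of assembly GRCr8 and held no Ensembl identifier in any row. The 31 lists of processes and cell types fixed before the data were examined could therefore not be tested, and their camera and fry tests and blocked fits were not run. The rule for named genes, also fixed before the data were examined, asked for a gene name, an adjusted p under 0.05, a mean of at least 1 CPM in a group and at least 75% of libraries beyond the median of the comparison group. The name could not be required. Of the 5 (metals against Ta) or 4 (other comparisons) largest rises and falls the rule takes, at most 2 of each are given per comparison, because identifiers alone were at hand. Named genes of Ni against Co and of Ta between 1 and 6 months are not given. Where a comparison called a single gene, it was named after its value was seen.

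Each comparison used the libraries of its own groups. Genes with low counts were removed with filterByExpr, which left 12034 to 13141 genes. TMM factors, robust dispersion estimates, glmQLFit with robust=TRUE and glmQLFTest of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) gave the tests, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Counts given with edgeR below are those of this fit unless another setting is named. The SE of a log2 fold change is its size over the square root of the F statistic. The median log2 fold change over all genes lay between -0.04 and 0.04. CPM values used TMM factors over all libraries, and log2 CPM a prior count of 2. The mean log2 CPM of a gene list was compared by exact two-sided permutation tests (scipy 1.17.1) with Benjamini-Hochberg adjustment over 30 tests. This measure and its lists were chosen after seeing the data. The 30 tests include the 2 comparisons by which the lists were chosen (exact permutation p = 0.000311 and 0.000155), whose outcome was fixed by that choice. Their low p-values lower the adjusted values of the other tests, and no adjustment without them was made.

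The test was checked on simulated counts with 200 genes changed in each comparison. It recovered 40% of 2-fold and 85% of 4-fold changes for Co against Ta at 3 months (12429 genes), 78% and 93% for P at 12 months (12179 genes) and 37% and 80% for DU at 3 months (12158 genes). In the simulation of Co at 6 months (12036 genes), 4 of 141 calls were false with edgeR and 39 of 196 with DESeq2. The simulated genes varied independently, with the dispersions edgeR had estimated and without shifts of whole libraries. These shares therefore need not hold for the real libraries.

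The alternatives fixed before the data were examined were DESeq2's size factors (RLE), no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, all 150 libraries in 1 model and the replicate number as a block. Added after seeing the data were leave-one-out fits, thinning to equal totals, library totals without TMM factors, leaving out 2 DU libraries together, limma voom without weights, and glmQLFit with legacy=FALSE or robust=FALSE. The last 3 were first tried on 4 comparisons while the data were being explored, along with DESeq2 and the weighted voom fit. Because of the time each fit took, 25 splits of the libraries, the real one included, were drawn per comparison. Within groups no pair of libraries matched within sampling noise, with a lowest chi-square per degree of freedom of 11.5. A count of 0 was given a floor of 3 counts. Floors cover counting error only.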

Results

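RNA was sequenced from the gastrocnemius muscle of male Sprague-Dawley rats that carried small metal cylinders in that muscle. Each rat had 4 cylinders, 2 in each limb, each 1 mm across and 2 mm long. The libraries fell into 19 groups by metal and by the time since surgery. Tantalum (Ta), the sham metal, cobalt (Co), a metal labelled P and depleted uranium (DU) were sampled at 1, 3, 6 and 12 months, and nickel (Ni) at 1, 3 and 6 months. The design text lists lead, Pb, among the sequenced metals and no other metal with that initial, so P is taken to be lead. The library labels do not spell this out, and the label P is kept here as written. The 150 libraries made 17 groups of 8 and 2 groups of 7, the latter being Ta at 1 month and Co at 6 months. Total counts ran from 12674115 to 21921859 per library with a median of 15778710. Of 32545 genes in the table, 25658 had a count in at least 1 library. Genes are given by Ensembl identifier because neither the files nor the reference table used paired identifiers with names. No gene was therefore placed in a process or a cell type here.

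Cobalt was compared with Ta of the same time to ask how the muscle around a cobalt cylinder differed from muscle around the sham metal. At 3 months 767 genes were higher and 34 lower with Co (adjusted p under 0.05, 12429 genes tested), and 724 of the rises and 8 of the falls were over 2-fold. The gene ENSRNOG00000048402 averaged 2510 ± 3740 CPM with Co and 0.407 ± 0.379 CPM with Ta (SD, n = 8 and 8), a log2 fold change of 12.60 ± 1.47 (SE, edgeR adjusted p = 0.0016). ENSRNOG00000050000 averaged 393 ± 501 CPM (SD, n = 8) with Co and had no count in any of the 8 Ta libraries, so that it was at least 15200-fold higher against a floor of 3 counts over the Ta group (edgeR adjusted p = 0.0119). Among the falls, ENSRNOG00000003171 averaged 17.7 ± 10.8 CPM with Co and 98.8 ± 136 CPM with Ta (SD, n = 8 and 8), a log2 fold change of -2.46 ± 0.68 (SE, edgeR adjusted p = 0.0404). ENSRNOG00000018674 averaged 0.762 ± 0.362 CPM with Co and 2.14 ± 0.669 CPM with Ta (SD, n = 8 and 8), a log2 fold change of -1.47 ± 0.33 (SE, edgeR adjusted p = 0.0164). All 8 Co libraries lay beyond the Ta median in the called direction for each of these 4 genes. At 3 months ENSRNOG00000003171 averaged 337 ± 766 CPM with Ni, 34.8 ± 27.3 CPM with P and 19 ± 10.7 CPM with DU (SD, n = 8 each). ENSRNOG00000018674 averaged 1.71 ± 0.982, 1.01 ± 0.44 and 0.963 ± 0.46 CPM there (SD, n = 8 each). In Ta the latter averaged 1.29 ± 0.539 CPM at 1 month (SD, n = 7). At 6 and 12 months it averaged 0.746 ± 0.597 and 0.803 ± 0.35 CPM in Ta (SD, n = 8 each).

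**Figure D1:**
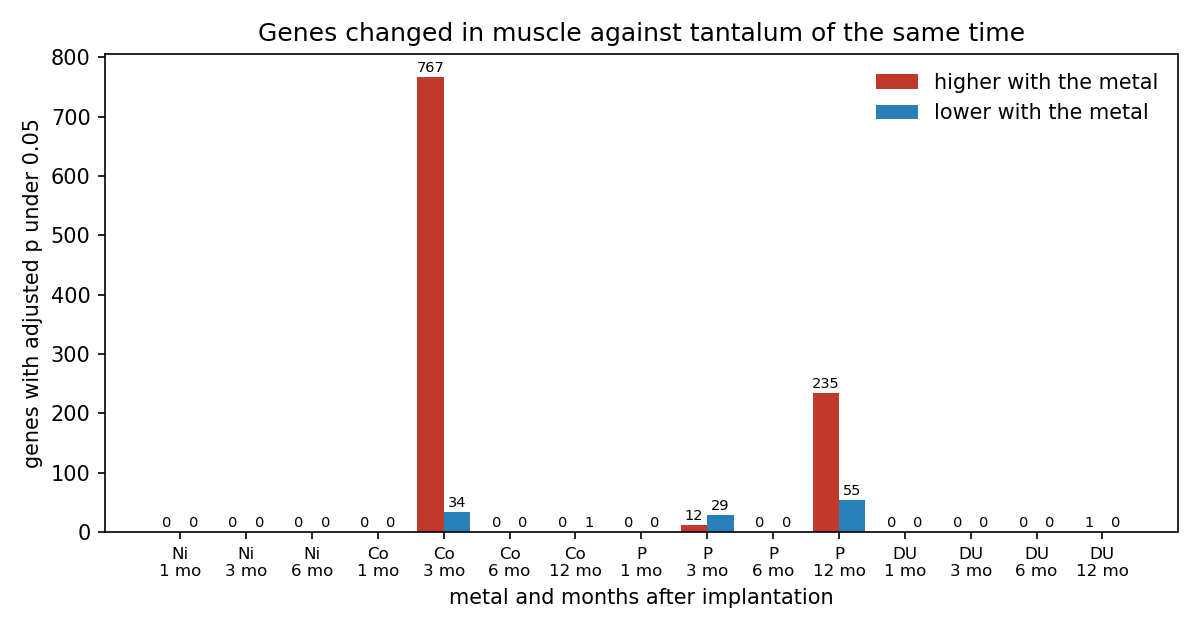
Number of genes with adjusted p under 0.05 against Ta of the same time (y axis) for each metal and month (x axis), with genes higher and lower with the metal as separate bars. The tallest bar is the 767 genes higher with Co at 3 months, followed by the 235 genes higher with P at 12 months.

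The genes that rose with Co at 3 months were mostly scarce in muscle with Ta. Of the 767, 224 averaged under 1 CPM over the 31 Ta libraries, 438 between 1 and 10 CPM, 102 between 10 and 100 CPM and 3 between 100 and 1000 CPM. None of the 94 genes of at least 1000 CPM was called, and their median log2 fold change was -0.55 (quartiles -0.71 and -0.39). The rise differed widely between the 8 Co libraries. The mean log2 CPM of the 767 genes was 5.05, 4.85, 4.82 and 4.09 in replicates 2, 8, 6 and 3, and 2.08, 1.99, 1.87 and 1.59 in replicates 7, 1, 4 and 5, against 0.70 to 1.86 in Ta at 3 months. The 10 most abundant genes took 15.5% to 22.5% of the counts in Co replicates 2, 8, 6 and 3. In Co replicates 7, 1, 4 and 5 they took 25.8% to 31.2%, and in the 8 Ta libraries 22.3% to 38.6%. Genes of at least 1 CPM numbered 12482 to 12798 in Co replicates 2, 8, 6 and 3. They numbered 11611 to 11799 in Co replicates 7, 1, 4 and 5, and 11132 to 11743 in the Ta libraries. Leaving out a single Co library moved the count of called genes to 365 without replicate 2 or 8, 380 without 6, 512 without 3, 1302 without 7, 1310 without 1, 1426 without 5 and 1534 without 4. limma voom with sample quality weights called 3 genes and the fit with the replicate number as a block called 1, while DESeq2 called 2387, the fit of all 150 libraries together 3268 and the fit without the filter on low counts 1515. Without TMM factors, a setting chosen after seeing the data, 2810 genes were called.

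**Figure D2:**
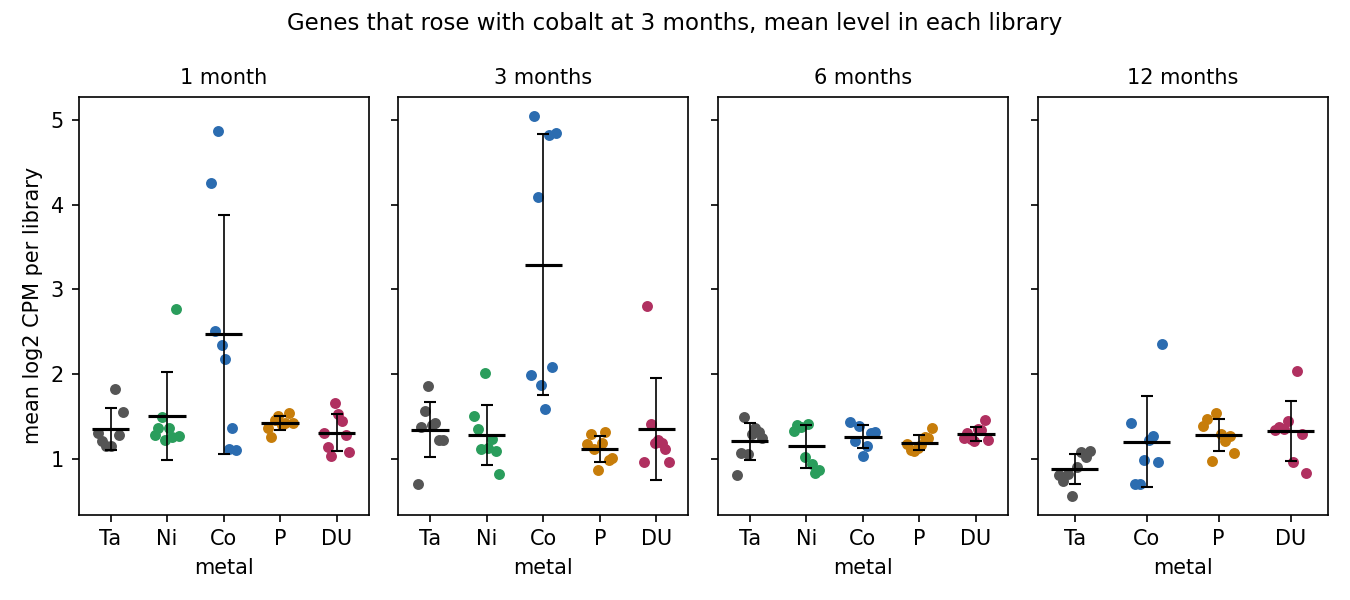
Mean log2 CPM of the 767 genes that rose with Co at 3 months (y axis) in each library (points) by metal (x axis) and month (panels), with the group mean (bar) and SD (whisker). The points with Co at 3 months run from 1.59 to 5.05 and those with Co at 1 month from 1.10 to 4.87, while with Co at 6 months they run from 1.03 to 1.43.

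At the other times Co gave few calls or none with edgeR, but more with some other fits. No gene passed at 1 month or at 6 months with edgeR, where 1820 and 818 genes had an unadjusted p under 0.05. DESeq2 called 995 and 51 genes in these comparisons, limma voom with sample quality weights 0 and 573, and the fit of all 150 libraries together 1697 and 1. Without Ta replicate 5 the 6 month count was 128. Co replicate 1 at 6 months had a TMM factor of 0.459, against 0.83 to 1.04 in its group, and a median correlation of 0.874 with its group, against 0.971 to 0.974, and without it the count stayed at 0. At 12 months the gene ENSRNOG00000009329, named after its value was seen, was lower with Co at 47.9 ± 11 CPM against 95.3 ± 18.5 CPM (SD, n = 8 and 8), a log2 fold change of -0.99 ± 0.14 (SE, edgeR adjusted p = 0.0182). In Ta this gene averaged 51.1 ± 18.1 CPM at 1 month (SD, n = 7), 97.4 ± 31 CPM at 3 months and 48.6 ± 20.9 CPM at 6 months (SD, n = 8 each), and at 12 months it averaged 50 ± 20.4 CPM with P and 54.5 ± 16.5 CPM with DU (SD, n = 8 each). It was the single call with edgeR. DESeq2 called 140 genes and limma voom with sample quality weights 166, while the fit of all 150 libraries together called 24 without this gene, whose adjusted p there was 0.266. The edgeR count reached 14 without Ta replicate 3, 13 without Ta replicate 8, 3 without Co replicate 1 and 2 without Ta replicate 7. No call was left without Ta replicate 4, 5 or 6 or without Co replicate 3, 6 or 8. The 767 genes chosen at 3 months averaged a log2 CPM of 2.47 ± 1.41 with Co at 1 month (SD, n = 8) and 1.35 ± 0.25 with Ta (SD, n = 7), with 5 of 8 Co libraries above every Ta library. The exact two-sided permutation test gave p = 0.0373, which became 0.14 after adjustment over 30 such tests. At 6 months the means were 1.26 ± 0.14 (SD, n = 7) and 1.20 ± 0.22 (SD, n = 8; exact permutation p = 0.569, adjusted 0.86), and at 12 months 1.20 ± 0.53 and 0.88 ± 0.18 (SD, n = 8 and 8; exact permutation p = 0.106, adjusted 0.289). The same 767 genes lay above Ta at 12 months with P, at 1.28 ± 0.19 (SD, n = 8; exact permutation p = 0.0014, adjusted 0.014), and with DU, at 1.33 ± 0.36 (SD, n = 8; exact permutation p = 0.00435, adjusted 0.0326), each with 6 of 8 libraries above every Ta library. Both tests share the 8 Ta libraries of 12 months, whose mean was below the 1.20 to 1.35 of Ta at the other times. The 30 tests also include those by which the lists were chosen, whose low p-values lower the adjusted ones. The adjusted 0.0326 with DU is therefore not taken as passed. Genes under 1 CPM in Ta had a median log2 fold change of 0.23 with P, 0.22 with DU and 0.17 with Co there, with 70.1%, 67.6% and 66.9% above 0. This class was set by a low level in Ta, and the filter on low counts keeps such genes more readily where they are higher with the metal. These shares are therefore not taken as support for a rise. Whether P or DU differed from Co in this list was not tested.

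Nickel was compared with Ta and, at the 3 times both were sequenced, directly with Co. No gene passed for Ni against Ta at 1, 3 or 6 months with edgeR, where 1517, 413 and 328 genes had an unadjusted p under 0.05. DESeq2 called 2, 5 and 1 genes, limma voom with sample quality weights none, and the fit of all 150 libraries together 35, 5 and 0. In simulated data the test recovered 56%, 58% and 64% of 2-fold changes and 92%, 80% and 94% of 4-fold changes in these 3 comparisons. Directly against Co at 3 months, 83 genes were higher and 1424 lower with Ni, 11 and 1123 of them by over 2-fold. That count was 647 to 2615 when single libraries were left out. It moved by over 1.5 times without Co replicate 1 (2514), 2 (647), 3 (954), 4 (2615), 6 (694) or 8 (662) and without Ni replicate 3 (930), 5 (934), 6 (1001), 7 (885) or 8 (975). limma voom with sample quality weights called 1 gene and the fit with the replicate number as a block called 0, while DESeq2 called 3082 and the fit of all 150 libraries together 3980. No gene differed between Ni and Co at 1 or 6 months with edgeR, where 3235 and 1640 genes had an unadjusted p under 0.05. DESeq2 called 1179 and 286 genes there, and limma voom with sample quality weights 0 and 492. The 1 month count was 1 without Co replicate 7. The 6 month count was 35 without Ni replicate 3, 33 without Co replicate 1 and 1 without Ni replicate 5.

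The P groups were compared with Ta at 4 times. At 12 months 235 genes were higher and 55 lower with P (12179 genes tested), 168 and 3 of them by over 2-fold. ENSRNOG00000009589 averaged 5.01 ± 5.69 CPM with P and 0.202 ± 0.219 CPM with Ta (SD, n = 8 and 8), a log2 fold change of 4.58 ± 0.79 (SE, edgeR adjusted p = 0.00687). ENSRNOG00000004635 averaged 4.36 ± 4.91 CPM with P and 0.295 ± 0.478 CPM with Ta (SD, n = 8 and 8), a log2 fold change of 3.86 ± 0.85 (SE, edgeR adjusted p = 0.0247), and its adjusted p was 0.0565 without the filter on low counts and between 0.00189 and 0.0565 over 6 alternatives. Among the falls, ENSRNOG00000002911 had a log2 fold change of -3.92 ± 0.75 (SE, edgeR adjusted p = 0.0124), with 0.324 ± 0.201 CPM against 4.98 ± 7.42 CPM (SD, n = 8 and 8), the Ta libraries reaching 22.9 CPM. At 12 months it averaged 0.574 ± 0.404 CPM with Co and 0.267 ± 0.287 CPM with DU (SD, n = 8 each). With DU at 3 months it averaged 19100 ± 52100 CPM (SD, n = 8), where single libraries ran from 0 to 148000 CPM. ENSRNOG00000018736 had a log2 fold change of -2.35 ± 0.56 (SE, edgeR adjusted p = 0.0368), with 1.29 ± 0.504 CPM against 6.65 ± 5.60 CPM (SD, n = 8 and 8). Its adjusted p was between 0.000236 and 0.293 over 6 alternatives and passed in 2 of them. The count was 138 without P replicate 4, 166 without P replicate 1 or Ta replicate 5, 171 without Ta replicate 4, 173 without Ta replicate 1, 189 without Ta replicate 3 and 465 without P replicate 8. The fit with the replicate number as a block called 44 genes, and the fit of all 150 libraries together 114, while DESeq2 called 664 and limma voom with sample quality weights 719.

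The mean log2 CPM of the 235 genes that rose with P at 12 months was 2.64 ± 0.35 with P and 1.40 ± 0.30 with Ta at 12 months (SD, n = 8 and 8). In Ta it had been 2.26 ± 0.22 at 1 month (SD, n = 7), where no library lay as low as the highest at 12 months, 2.02 ± 0.46 at 3 months and 2.43 ± 0.42 at 6 months (SD, n = 8 each). With P it was 2.65 ± 0.27, 2.08 ± 0.25 and 2.47 ± 0.16 at those times (SD, n = 8 each). In libraries not used to choose the genes, P lay above Ta at 1 month (exact permutation p = 0.0103, adjusted 0.044, with 4 of 8 libraries above every Ta library). So did Co at 3 months, at 3.03 ± 0.80 (SD, n = 8; exact permutation p = 0.00808, adjusted 0.0412, with 5 of 8 above). With Co at 12 months it was 1.90 ± 0.67 and with DU 2.27 ± 0.72 (SD, n = 8 each), the latter above Ta at an exact permutation p of 0.00824 (adjusted 0.0412 over 30 tests), in 6 of 8 libraries above every Ta library. The comparisons at 12 months share the Ta libraries by which the genes were chosen. The 30 tests also include those by which the lists were chosen, whose low p-values lower the adjusted ones. The adjusted 0.044 and 0.0412 are therefore not taken as passed.

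**Figure D3:**
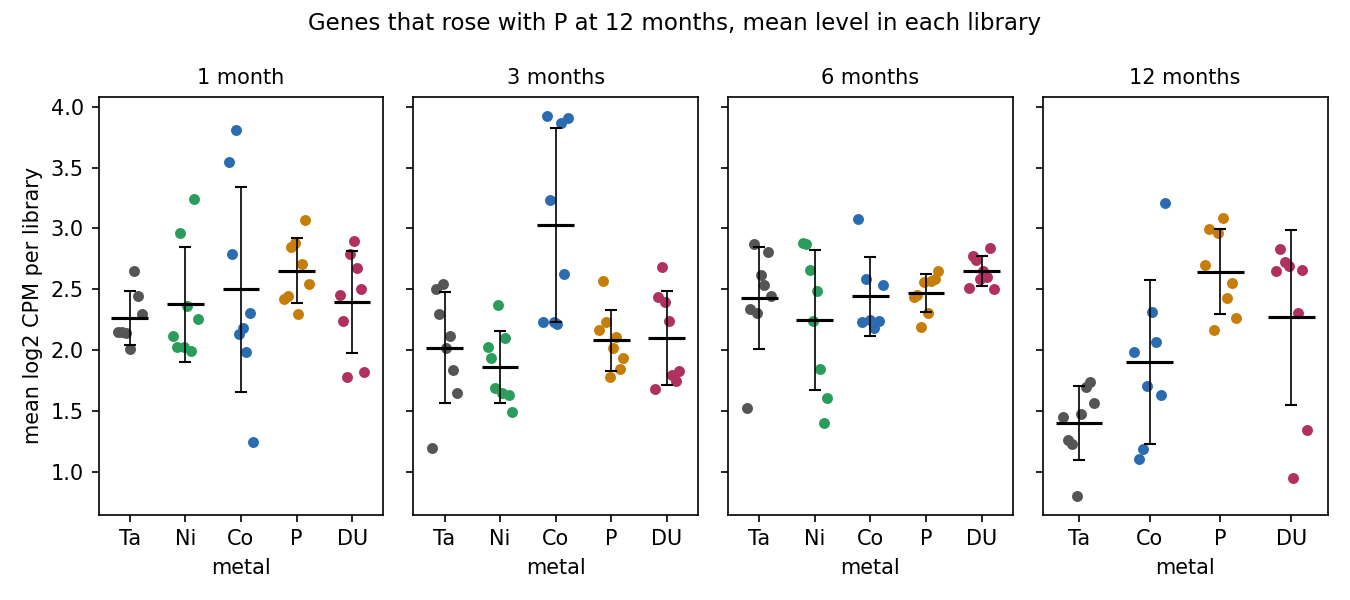
Mean log2 CPM of the 235 genes that rose with P at 12 months (y axis) in each library (points) by metal (x axis) and month (panels), with the group mean (bar) and SD (whisker). Ta at 12 months lies between 0.80 and 1.74 and P at 12 months between 2.16 and 3.09, while Ta at 1 month lies between 2.00 and 2.65.

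At 3 months 12 genes were higher and 29 lower with P. ENSRNOG00000047351 had a log2 fold change of 2.44 ± 0.51 (SE, edgeR adjusted p = 0.0499), at 8.9 ± 10.6 CPM with P, where a library reached 34.4 CPM, and 1.63 ± 0.745 CPM with Ta (SD, n = 8 and 8). ENSRNOG00000011181 had one of 2.12 ± 0.27 (SE, edgeR adjusted p = 0.00365), at 1.29 ± 0.233 CPM with P and 0.283 ± 0.124 CPM with Ta (SD, n = 8 and 8). ENSRNOG00000043451 had a log2 fold change of -5.29 ± 1.07 and ENSRNOG00000019440 of -1.82 ± 0.38 (SE, edgeR adjusted p = 0.0499 for both). The former averaged 0.693 ± 0.652 CPM with P and 26.6 ± 41.1 CPM with Ta (SD, n = 8 and 8), where it ran from 0.275 to 118 CPM, and the latter 1.14 ± 0.366 and 3.98 ± 2.64 CPM (SD, n = 8 and 8). With DESeq2's size factors the adjusted p of ENSRNOG00000047351 and ENSRNOG00000043451 was 0.0569. With DU at 3 months these genes, in the order given, averaged 3.99 ± 1.07, 1.06 ± 0.905, 0.912 ± 0.76 and 1.29 ± 0.498 CPM (SD, n = 8). With Ni they averaged 2.48 ± 2.08, 0.181 ± 0.0845, 8.95 ± 16.1 and 2.61 ± 1.44 CPM (SD, n = 8). With Co they averaged 2.25 ± 0.748, 0.754 ± 0.781, 6.66 ± 8.84 and 22 ± 22.3 CPM (SD, n = 8). P against DU at 3 months gave 0 genes, so the calls are not shown to be particular to P. Leaving out any 1 of the 16 libraries moved the count by over 1.5 times. It was 1466 without Ta replicate 1, 574 without Ta replicate 3, 353 without P replicate 4, and 1 to 5 without any other library. The count was 13 with DESeq2's size factors, 12 without the filter on low counts, 2 with the replicate number as a block, 994 with DESeq2 and 3970 with limma voom with sample quality weights. No gene passed for P at 1 or 6 months with edgeR, where 1021 and 895 genes had an unadjusted p under 0.05. DESeq2 called 33 and 20 genes there and limma voom with sample quality weights none. The 1 month count was 1 without Ta replicate 6.

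Depleted uranium was compared with Ta at 4 times. The gene ENSRNOG00000003172, named after its value was seen, was the single call at 12 months, with 16.9 ± 4.35 CPM against 6.02 ± 1.58 CPM (SD, n = 8 and 8), a log2 fold change of 1.5 ± 0.20 (SE, edgeR adjusted p = 0.0104), and with all 8 DU libraries above the Ta median. The count was 20 without DU replicate 5 and 5 without DU replicate 8 or Ta replicate 8. With both DU replicates 5 and 6 left out, a setting chosen after seeing the data, 127 genes passed. DESeq2 called 190 genes at 12 months, limma voom with sample quality weights 366, the fit of all 150 libraries 747 and the fit with the replicate number as a block 0. No gene passed at 1, 3 or 6 months with edgeR, where 1004, 3223 and 1591 genes had an unadjusted p under 0.05. DESeq2 called 20, 1440 and 13 genes at these times and limma voom with sample quality weights 0, 4664 and 0. The fit of all 150 libraries together called 4, 3466 and 3, and glmQLFit with legacy=FALSE called 236 at 3 months. The edgeR count of 0 at 3 months rose to 744 without DU replicate 2, 812 without Ta replicate 1, 141 without Ta replicate 3 and 89 without DU replicate 1. The median correlation of DU replicate 2 with the rest of its group was 0.605.

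Whether the effect of a metal differed between its last time and 1 month was tested by an interaction term. The gene ENSRNOG00000003172 passed for DU, where the difference from Ta at 12 months exceeded that at 1 month by 1.5 ± 0.24 on the log2 scale (SE, edgeR adjusted p = 0.00652). With all 150 libraries in the fit 213 genes passed and this gene did not (adjusted p = 0.274). Its mean with DU was 18.4 ± 3.57 CPM at 1 month and 16.9 ± 4.35 CPM at 12 months (SD, n = 8 each), while with Ta it was 18.4 ± 2.36 CPM (SD, n = 7) and 6.02 ± 1.58 CPM (SD, n = 8). At 12 months it averaged 18.9 ± 10.5 CPM with P and 13 ± 11.6 CPM with Co (SD, n = 8 each). No gene passed for Ni, Co or P with edgeR, where 2392, 1491 and 1142 genes had an unadjusted p under 0.05. DESeq2 called 7, 206 and 13 genes for these metals and 43 for DU, and limma voom with sample quality weights 0, 0 and 1 and, for DU, 1.

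Time since surgery was compared within the Ta groups, in which age, cohort and time with the cylinder run together. Between 1 and 12 months 944 genes rose and 1220 fell (12219 genes tested), 137 and 436 of them by over 2-fold. ENSRNOG00000002911 rose from 0.050 ± 0.0629 CPM (SD, n = 7) to 4.98 ± 7.42 CPM (SD, n = 8), a log2 fold change of 6.40 ± 1.02 (SE, edgeR adjusted p = 0.00129). The Ta libraries at 12 months ran from 0.726 to 22.9 CPM, and at 3 months 7 of 8 held none while a library held 7.38 CPM. At 12 months this gene averaged 0.574 ± 0.404, 0.324 ± 0.201 and 0.267 ± 0.287 CPM with Co, P and DU (SD, n = 8 each). ENSRNOG00000038406 rose from 0.183 ± 0.178 CPM (SD, n = 7) to 2.50 ± 0.942 CPM (SD, n = 8), a log2 fold change of 3.72 ± 0.51 (SE, edgeR adjusted p = 0.000358). ENSRNOG00000052173 had a log2 fold change of -3.02 ± 0.54 (SE, edgeR adjusted p = 0.00212), from 1.23 ± 0.529 CPM (SD, n = 7) to 0.142 ± 0.181 CPM (SD, n = 8). ENSRNOG00000003622 had one of -2.76 ± 0.85 (SE, edgeR adjusted p = 0.0384), but 1 library at 1 month held 55.8 CPM of it and its adjusted p was 0.138 with DESeq2 and between 0.0165 and 0.174 over 6 alternatives. Of the genes that rose, 569 averaged 10 to 100 CPM and 274 averaged 1 to 10 CPM over the Ta libraries. Of those that fell, 416 and 730 did. Between 1 and 6 months 503 genes rose and 702 fell, and the count moved by over 1.5 times without Ta 1 month replicate 1 (569), 2 (704), 4 (741) or 8 (601) and without Ta 6 month replicate 3 (718), 5 (2238) or 7 (761). No gene was called between 1 and 6 months with the replicate number as a block, while 2103 were between 1 and 12 months. The fit of all 150 libraries together called 891 between 1 and 12 months. Between 1 and 3 months 1 gene, ENSRNOG00000043192, named after its value was seen, was called, with a log2 fold change of -1.25 ± 0.19 (SE, edgeR adjusted p = 0.0444) and 23.4 ± 4.42 CPM against 56.0 ± 17.3 CPM (SD, n = 8 and 7). That count was 0 to 5 with single libraries left out and 511 with limma voom with sample quality weights.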

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

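Of the tests in this part, those of RNA from other cells and of the DU replicate, and the counts of other splits, were set after the values they bear on had been seen at least in part. Thinning, the fit without TMM factors and the direct comparisons of metals were set before their values were seen, on patterns already noticed. The share without TMM factors was added to the test of RNA from other cells after the share with them had been seen, and the direct comparison of P and Co was at one stage read more strictly after its value had been seen, before the reading written in advance was restored.

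The rise of 767 genes with Co at 3 months was strong in some of the 8 libraries and weak in others. Depth does not account for the rise against Ta, since 93.8% of the called genes were called again after thinning to equal totals. Nor do the TMM factors, since without them the median log2 fold change of the risen genes was 2.90. The factors ran from 0.986 to 1.89 with Co and 0.798 to 1.28 with Ta, so leaving them out could hardly have lowered it. Neither value bears on the difference between the 8 Co libraries. RNA from other cells or tissue in the piece may contribute. Of the 94 genes of at least 1000 CPM in Ta, 0% lay above 0 in log2 fold change with TMM factors, as that needs, and 13.8% without them. Both shares move with the scaling of whole libraries, so neither decides, and no marker list could be matched, so this cannot be told apart from a change within the muscle. An effect of cobalt itself stays open too, as does a difference in how close each piece lay to a cylinder, which was not tested.

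The genes called with P at 12 months raised the question whether P or the Ta libraries of that time stood apart. Depth does not account for the calls, since 82.4% were made again after thinning. Directly against Co of the same time 0% of the called genes passed in the same direction, as written in advance for a Ta group set apart from all other metals, which may therefore be the source, though that comparison called 7 genes in all. The risen genes' median of 0.50 there says nothing against it, since they were picked for a high level with P. Against Ta the same genes had medians of 1.31 with P, 1.06 with DU and 0.62 with Co, with 99.5% above 0 for Co, which goes with Ta standing apart, though the genes were also picked for a low level in these Ta libraries. Against DU 0% passed, with a median of 0.24, so an effect of P cannot be told apart from a batch shared by P and DU, because the labels give no batch. The effect of P itself stays among the open explanations, since none of these values excludes it.

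Replicate 2 of DU at 3 months had a profile unlike its group. Low depth was excluded by its total of 19287675 counts, above its group's median, and a swap with another library of the series by a highest correlation of 0.693 with any other library. Another tissue in place of the muscle piece may be the source. Of the 50 genes most abundant in the other libraries, 32 lay under 1% of their median level there, which argues against a mixture with an appreciable share of ordinary muscle. Of genes of at least 100 CPM there, 1 stayed under 1 CPM in every other library, short of the bound set for it, which a trace in any library breaks, while 398 were over 10 times the highest other library, a count no prediction had named. Without gene names no tissue could be named, so another tissue cannot be told apart from a piece in which the muscle itself had been replaced. No biological explanation was tested.

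Single libraries far from the rest of their group were looked for in 76 sets of per-library values and 10 were found, where chance marks about 1 in 20. For the mean log2 CPM of the genes that rose with Co at 3 months, Ni 1 month replicate 7 stood at 2.77 against 1.22 to 1.49 in the rest of its group, Co 12 months replicate 8 at 2.35 against 0.69 to 1.42, and DU 3 months replicate 2 at 2.80 against 0.96 to 1.41. For the genes that rose with P at 12 months, Ta 6 months replicate 1 stood at 1.52 against 2.30 to 2.87. Total counts stood apart in P 1 month replicate 6 (18436567), P 3 months replicate 7 (20003685), P 12 months replicate 8 (21921859), DU 6 months replicate 8 (21197192) and DU 12 months replicate 8 (16947685). In DU 3 months replicate 5 the 10 most abundant genes took 40.3% of the counts, against 25.6% to 28.6% in its group. Among named genes, the log2 CPM of ENSRNOG00000011181 was -0.09 in P 3 months replicate 7 against 0.35 to 0.74, and that of ENSRNOG00000019440 was -0.97 in P 3 months replicate 6 against 0.13 to 0.80. ENSRNOG00000003172 stood at 3.08 in DU 12 months replicate 8 against 3.87 to 4.43, and ENSRNOG00000003622 at 5.81 in Ta 1 month replicate 5 against 0.15 to 1.81.

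A difference between times was called for 1 gene, ENSRNOG00000003172, whose difference between DU and Ta was larger at 12 months than at 1 month. Its mean with DU was 18.4 CPM at 1 month and 16.9 CPM at 12 months and with Ta 18.4 and 6.02 CPM, while at 12 months P stood at 18.9 CPM and Co at 13 CPM. Of the splits of its libraries, 6 of 25 gave as many genes, with a highest of 10 in the others, so chance is not excluded. With all 150 libraries in the fit 213 genes passed but not this gene.

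Other splits of the same libraries were fitted for every comparison, 25 each with the real one included. The lowest share that 25 splits can give is reached where 1 split, the real one, gave as many genes. Such a result comes about 1 time in 25 comparisons by chance, so it alone excludes chance nowhere. It was reached for P at 12 months (290 genes, highest other 0). It was also reached for Ta between 1 and 6 months (1205, highest other 1) and between 1 and 12 months (2164, highest other 0). These counts stood far above those of the other splits, which argues against chance. Yet for Ta between 1 and 6 months the count was 0 with the replicate block and 569 to 2238 with single libraries left out. For P at 12 months it was 44 with the block and 138 to 465 with single libraries left out. For Co at 12 months (1 gene, highest other 0) and P at 3 months (41, highest other 16) the real split alone gave as many too, with counts nearer to those of other splits. The Co call ended without any 1 of 6 libraries, and the P count was 1 to 5 without most single libraries and 2 with the replicate block. No argument against chance is therefore made for either. Nor was chance excluded for Co at 3 months, where 2 splits gave as many genes (801, highest other 1389), Ni against Co at 3 months (2 splits, 1507, highest other 1615), DU at 12 months (2 splits, 1, highest other 1) or Ta between 1 and 3 months (4 splits, 1, highest other 1465). Why other splits called more genes than the real one in some comparisons was not tested. For comparisons with 0 genes all 25 splits gave as many, with highest others of 106 for Co at 1 month, 56 for Ni against Co at 1 month, 48 for P at 6 months and 0 to 2 for the rest.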

How the results depend on the processing

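Settings beyond the 6 fixed ones were chosen after seeing the data. The causes of the moves below were not tested, except that fewer libraries enter a leave-one-out fit. Tests of gene lists were not run because no identifier had a name, and the overlap between metals was not run because no 2 metals had 50 calls each at the same time. Leave-one-out was not run for the interactions. Counts named below moved by over 1.5 times, and all others stayed within that.

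With the DESeq2 Wald test the counts against Ta were 2, 5 and 1 for Ni at 1, 3 and 6 months, 995, 2387, 51 and 140 for Co at 1, 3, 6 and 12 months, 33, 994, 20 and 664 for P, and 20, 1440, 13 and 190 for DU. The interactions gave 7 for Ni, 206 for Co, 13 for P and 43 for DU. Ta between 1 and 3 months gave 12 and between 1 and 6 months 2134, and Ni against Co gave 1179, 3082 and 286 at 1, 3 and 6 months. All 801 genes called for Co at 3 months and all 290 for P at 12 months were among these calls, but 784 and 88 were with all libraries in 1 model, 764 and 195 without the filter, 3 and 281 with weighted voom and 1 and 43 with the replicate block.

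With all 150 libraries in 1 model the counts were 35 and 5 for Ni at 1 and 3 months, 1697, 3268, 1 and 24 for Co, 3, 74, 2 and 114 for P, and 4, 3466, 3 and 747 for DU. The interactions gave 8, 239, 1 and 213 for Ni, Co, P and DU. Ta between 1 and 3 months gave 4 and between 1 and 12 months 891, and Ni against Co gave 3434, 3980 and 1.

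With limma voom with sample quality weights the counts were 3, 573 and 166 for Co at 3, 6 and 12 months, 3970 and 719 for P at 3 and 12 months, 4664 and 366 for DU at 3 and 12 months, 1 for the P interaction, 511 and 2211 for Ta between 1 and 3 or 6 months, and 1 and 492 for Ni against Co at 3 and 6 months. Without weights voom gave 2 for Co at 3 and at 12 months, 1 for P at 3 months, 1 for the Co and the P interaction, and 0 for Ta between 1 and 3 months and for Ni against Co at 3 months.

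Without the filter on low counts Co gave 1515 at 3 months and 2 at 12 months, and P gave 12 at 3 months. DESeq2's size factors moved P at 3 months to 13. With legacy=FALSE the counts were 2 for Co at 12 months, 76 for P at 3 months, 236 for DU at 3 months, and 1, 3 and 2 for the Ni, Co and P interactions. With robust=FALSE they were 12 for P at 3 months and 2 for the Co interaction. Without TMM factors Co at 3 months gave 2810, and leaving out DU 12 month replicates 5 and 6 gave 127.

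No full pairing by replicate number was seen, since in no comparison did every pair of like number correlate above 0.1, and in none did every library correlate best with its own number. A partial pairing is not excluded. For P at 3 months 6 of 8 pairs lay above 0.1 (median 0.26). For Co at 3 months 5 of 8 did, and 3 libraries correlated best with their own number. For P at 12 months and for Ni against Co at 3 months 0 of 8 pairs lay above 0.1. With the replicate block the counts were 1 and 3 for Co at 3 and 12 months, 2 and 44 for P at 3 and 12 months, 0 for DU at 12 months, 0 for Ta between 1 and 3 or 6 months, and 1 and 0 for Ni against Co at 1 and 3 months. It changed no other call by as much.

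With single libraries left out the counts ran from 365 to 1534 for Co at 3 months, 0 to 128 at 6 months and 0 to 14 at 12 months, 0 to 1, 1 to 1466 and 138 to 465 for P at 1, 3 and 12 months, and 0 to 812 and 1 to 20 for DU at 3 and 12 months. They ran from 0 to 5 and 569 to 2238 for Ta between 1 and 3 or 6 months, and 0 to 1, 647 to 2615 and 0 to 35 for Ni against Co at 1, 3 and 6 months.

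No named gene changed direction. Of 20 calls, 19 passed with DESeq2, 17 with its size factors, 16 with all libraries, 15 with weighted voom, 14 without the filter and 8 with the replicate block. By the unadjusted exact permutation p, the mean of the Co list kept its side of 0.05 in all 3 comparisons under each of 4 other lists or scalings. Of 46 leave-one-out values, 10 moved above 0.05, all for Co at 1 month, whose p adjusted over 30 tests had not passed (0.14), and 2 moved below it, both for Co at 12 months.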

Other observations

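These comparisons were chosen after the change over time in Ta had been seen. Changes between 1 and 12 months were computed within Co, P and DU, whose libraries are not shared with Ta. Age, cohort and time with the cylinder run together in these groups too, and no batch is known. The source of any sharing therefore cannot be told. With Co 963 genes rose and 1226 fell among 12056 genes tested in both, and 450 of the rises and 488 of the falls were also called in Ta, where independent lists of these sizes would share 74.6 and 123. With P 663 genes rose and 730 fell, sharing 368 and 447 with Ta against 51.2 and 73.3 from independent lists. With DU 69 rose and 92 fell, sharing 38 and 69 against 5.36 and 9.25. Genes called in both in opposite directions numbered 2 for Co, 2 for P and 0 for DU. Of the genes called in Ta, 94.2% had the same sign with Co, 93.4% with P and 78.4% with DU. Across genes, which are not independent replicates, the log2 fold changes correlated with those of Ta at r = 0.59, 0.62 and 0.33. The DU libraries at 12 months include replicates 5 and 6, with TMM factors of 1.48 and 1.56, against 0.971 to 1.08 in the others. Their median correlations with the group were 0.927 and 0.841, against 0.966 to 0.972. The DU change over time was not computed without them, so its smaller counts need not mean a smaller change.

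ENSRNOG00000048402, scarce in Ta at every time (means of 0.407 to 0.802 CPM), averaged 603 ± 1190 CPM with Co at 1 month (SD, n = 8), 3.37 ± 5.58 CPM at 6 months (SD, n = 7) and 0.604 ± 0.847 CPM at 12 months (SD, n = 8). Outside Co it averaged 88.6 ± 216 CPM with Ni at 3 months (SD, n = 8, up to 620 CPM), and single libraries reached 46.1 CPM with Ni at 1 month and 46.4 CPM with DU at 6 months. ENSRNOG00000050000 averaged 81.1 ± 140, 1.32 ± 1.55 and 0.067 ± 0.167 CPM at these times (SD, n = 8, 7 and 8). ENSRNOG00000009589 and ENSRNOG00000004635, called with P at 12 months, averaged 6.53 ± 7.50 and 11.4 ± 10.9 CPM in Ta at 6 months (SD, n = 8), above their means with P at 12 months, and 3.96 ± 3.21 and 4.24 ± 4.56 CPM with DU at 12 months (SD, n = 8).

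Direct comparisons at 12 months called 7 genes for P against Co, 1 of them higher and 6 lower with P, and 0 for P against DU and for DU against Co, where 6.06% and 8.31% of genes had an unadjusted p under 0.05. At 3 months edgeR called 2 genes for P against Ni and 0 for DU against Ni, though 21.5% and 24.8% of genes had an unadjusted p under 0.05, against 6.96% for P against DU and 3.41% for Ni against Ta. These DU libraries include replicate 2, whose profile was unlike its group. Without it, a setting chosen after seeing the data, 503 genes were higher and 445 lower with DU than with Ni, and P against DU still gave 0, with 3.01% of genes at an unadjusted p under 0.05.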
